A study of Mus musculus with 4 samples.

How the data were processed

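RNA from isolated pancreatic islets was measured on 4 Illumina mouse bead arrays, 2 of wild type mice and 2 of mice in which the bone morphogenetic protein receptor gene Bmpr1a was knocked out under Pdx1 control. Per the labels, all mice were 12 weeks old and on a C57BL/6 background, the RNA was extracted with Trizol, and the labelled cRNA carried biotin. Groups and replicate numbers were taken from the labels. The labels do not say whether the samples of a genotype came from separate mice, pools or extractions, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

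The deposited scanner table holds, per the file headers, for each array and probe a mean bead intensity on a linear scale, the standard error over its beads, the number of beads and a detection p-value. The detection p-value deposited by the authors compares a probe with the negative control beads, and the intensity values span 34.9 to 40522 without further scaling. The scanner table has 46632 probes. The second deposited table holds the authors' processed values of 46614 of these probes on a log2 scale, with array medians of 6.35 for wild type 1, 6.35 for wild type 2, 6.35 for knockout 1 and 6.34 for knockout 2. Set against the scanner values, the wild type 1 column equals the log2 of the raw intensity to within 5e-09, and each other column keeps the order of its own raw intensities (lowest rank correlation 1). The processed values are therefore log2 intensities that are not centred, and the method that brought the arrays to a common distribution is not given in the sources used here.

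Background was corrected with the normexp model of limma 3.58.1 in R 4.3.3, fitted through the detection p-values, with an offset of 16, followed by log2 and quantile normalization over all probes. A probe was tested when its detection p was below 0.05 on both arrays of at least 1 genotype, which left 15639 probes. The knockout was compared with the wild type by lmFit and eBayes (6.24 degrees of freedom in total), and p-values were adjusted by the Benjamini-Hochberg method over all tested probes, with a threshold of 0.05. Changes are knockout minus wild type on the log2 scale, given with the standard error of limma's fit. The offset shrinks changes of dim probes. Where a gene's probe was not well above background on either array of a genotype, the change is given as a bound. The bound sets the mean of the brighter genotype against the mean of, per array, the higher of the lowest detected value and the probe's own value.

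Probe names came from the platform annotation deposited for the array, which gave 1 symbol for 29965 probes and several for 10, and did not list 16657 probes, which stayed unnamed. Of the named probes, 29910 had a gene identifier that was found in the RefSeq gene table of assembly GRCm38.p6, and no symbol needed an update. A gene was represented by its tested probe with the highest mean value, and 9352 genes were tested. In 19 genes, different probes passed the test in opposite directions. Counts of list members rest on this brightest probe, and in 19 list genes it did not pass while another tested probe did.

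Before the data were examined, 29 gene lists were fixed, and 654 of their 760 entries matched a gene on the array. The 26 lists with at least 5 tested genes were tested as sets with camera at a preset correlation of 0.01, adjusted over the 26 lists. Members were also adjusted over the list alone. The genes named were fixed by a rule: Bmpr1a, the hormone and beta cell genes Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Mafa and Slc2a2, Id1 to Id4, the 10 largest rises and 10 largest falls among genes past the threshold with no overlap between genotypes, up to 4 members of each list past the test, the 2 largest changes where fewer than 2 passed, and each measured sex-linked gene. Genes outside the rule, named because a count held 5 or fewer or to show spread between arrays, were chosen after their values were seen. Ins1 and Mafa had no probe under these symbols and were not analysed here, and a further gene of the rule is not reported here.

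The replicates were compared before averaging. In the wild type pair 24.3% and in the knockout pair 35.5% of tested probes differed by more than 1.96 standard errors of their beads, where bead noise alone gives 5%. Repeat arrays of the same RNA could also differ by more than bead noise, so these shares do not show that the arrays of a genotype hold separate samples. The fit was tested on simulated data for the comparison of 2 knockout with 2 wild type arrays, with 200 of 15639 probes changed. It recovered 0% of probes changed by 0.5 on the log2 scale, 46% of those changed by 1, 100% of those changed by 2 and 100% of those changed by 4, and 5.39% of its calls were unchanged probes. The simulation changed far fewer probes than the 3988 called in the data, so its adjusted threshold was stricter. These rates therefore do not give the recovery in the data, where changes below 0.5 also passed, such as Id3 at -0.49. A simulated set shifted by 0.7 was called, and 0 of 20 unshifted sets were. The simulated probes were independent, while in the data the estimated correlation was 0.68 within the acinar list. The simulation therefore does not show how often lists of correlated genes would be called falsely.

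The alternatives were no background correction, an offset of 50, median scaling, cyclic loess, the authors' processed values, no filter, detection p under 0.01 on all 4 arrays, the replicate number as a block, an intensity trend in eBayes, each array left out in turn, an adjusted p under 0.10, 1 probe per gene, 2-fold in place of 1.5-fold, an estimated correlation in camera, fry, and the probe with the lowest detection p. The files used here name no slides, so a slide block was not run. With 1 array left out, the lone array of a genotype is assumed to vary like the pair of the other.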

Results

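Islet RNA of 12-week-old wild type mice and of mice lacking Bmpr1a in cells that had expressed Pdx1, a transcription factor of the developing pancreas and of beta cells, was profiled on 4 arrays, 2 per genotype. Bmpr1a encodes a type I receptor for bone morphogenetic proteins (Bmp). The comparison asks which islet transcripts differ between these knockout mice and wild type mice. The labels do not say whether the wild type mice carried a Cre transgene, which is used to delete genes in chosen cells. An effect of such a transgene therefore cannot be told apart from that of the deletion. Between 14785 and 16171 of the 46632 probes were detected per array, and median raw intensities lay between 76.8 and 81.5. Across tested probes, normalized log2 values correlated at 0.991 between the wild type arrays, at 0.987 between the knockout arrays and at 0.924 to 0.938 between genotypes, where probes are not independent replicates.

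The Bmpr1a transcript itself was measured by 1 probe above background. Its raw intensity was 793 and 851 on wild type arrays 1 and 2, and 887 and 687 on knockout arrays 1 and 2. On the normalized log2 scale Bmpr1a was 9.68 ± 0.01 in wild type and 9.41 ± 0.20 in knockout islets (SD, n = 2), a change of -0.28 ± 0.14 (SE) that did not pass the test (adjusted p = 0.204). Without knockout 1 the change was -0.42 and without knockout 2 it was -0.13, neither past the test (adjusted p = 0.0925 and 0.529). With median scaling the value was 0.01, where the median of all tested probes was 0.21. Another Bmpr1a probe was not well above background on any array. The position of these probes relative to the deleted part of the gene is not known here, so the value does not check the genotype labels.

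The transcripts that rose most in knockout islets included both tryptophan hydroxylases, the enzymes that start serotonin synthesis. Tph1, not well above background in wild type islets, was at least 29.4-fold higher (adjusted p = 2.66e-05), and Tph2 rose by 3.74 ± 0.25 on the log2 scale (SE, adjusted p = 0.000362). The leading probe of Lrrc55, an auxiliary subunit of potassium channels, was at least 33.4-fold higher (adjusted p = 5.81e-05). Its other tested probe rose by 2.93 on the log2 scale, past the test. The small GTPase gene Rerg was at least 14.6-fold higher (adjusted p = 0.000859). Sftpd, which encodes surfactant protein D, rose from 9.70 ± 0.08 to 13.88 ± 0.12 (SD, n = 2), and the neurotrophin receptor gene Ngfr from 6.13 ± 0.27 to 10.11 ± 0.50. Dnah8, a dynein heavy chain gene detected on 1 of the 2 wild type arrays, rose by 4.83 ± 0.18, and Ugt1a7c, likewise detected on 1, by 3.81 ± 0.24. Genes of the Ugt1a family share exons, so the Ugt1a7c probes cannot be assigned to it alone. The leading probe of the matrix gene Matn2 was at least 14.3-fold higher, with its 3 probes ranging from 0.50 to 4.33, and that of the chloride channel gene Cftr at least 6.08-fold, while its other tested probe changed by -0.22.

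The transcripts that fell most included several genes of B cells and plasma cells. Slpi, a secreted protease inhibitor, was at least 62.4-fold lower in knockout islets (adjusted p = 0.000161). Mzb1, a chaperone of antibody-secreting cells, fell by 6.07 ± 0.65 on the log2 scale (SE, adjusted p = 0.00183), with normalized values of 5.01 and 7.19 on knockout arrays 1 and 2. The B cell coactivator gene Pou2af1 was at least 22.7-fold lower, the B cell activating factor receptor gene Tnfrsf13c at least 9.87-fold and Lrmp at least 13.3-fold. Cd79b, part of the B cell receptor, fell by 4.72 ± 0.30, Klhl6 fell by 4.60 ± 0.13 and S1pr2 fell by 4.19 ± 0.17, although another Klhl6 probe fell by 0.90. Outside these, Gdpd3 was at least 22.1-fold lower and Reln, an extracellular matrix glycoprotein gene, at least 14.4-fold.

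**Figure D1:**
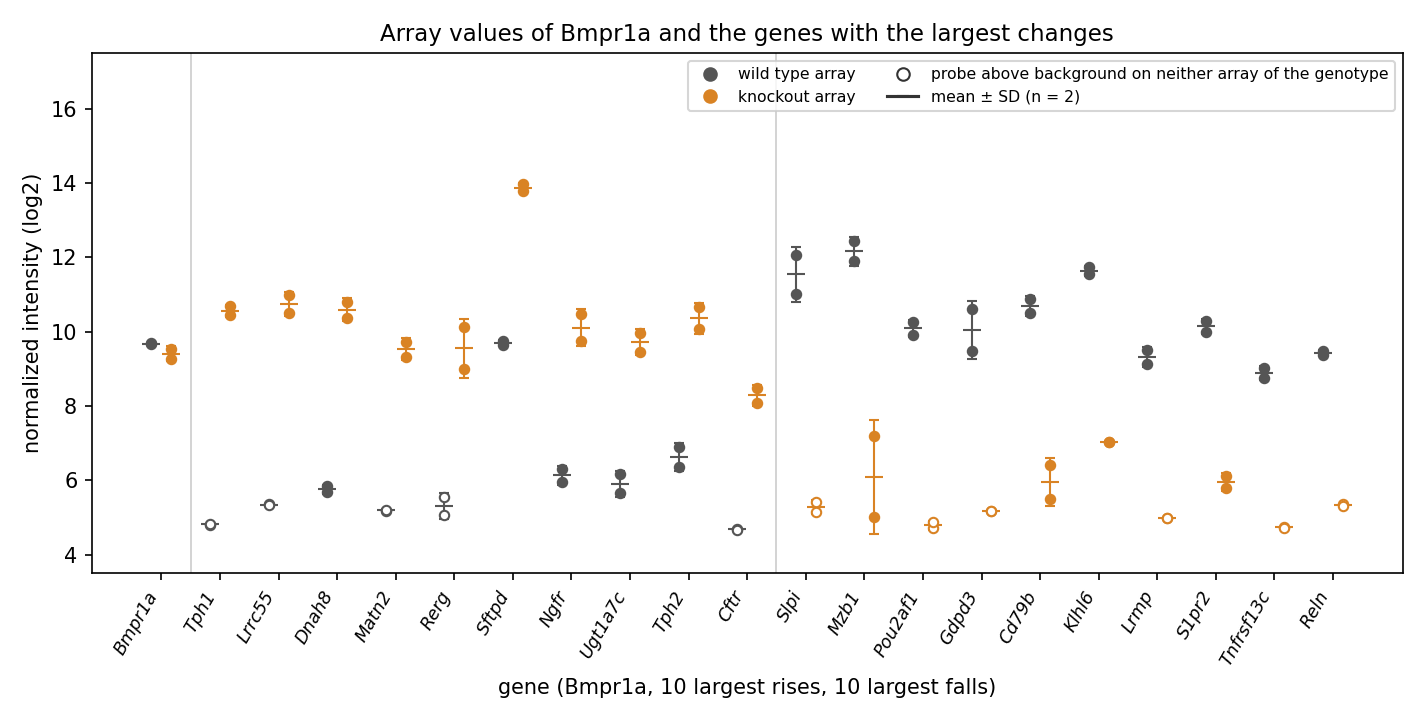
Normalized log2 intensity (vertical axis) of Bmpr1a, the 10 genes with the largest rises and the 10 with the largest falls (horizontal axis), with 1 point per array, wild type in grey and knockout in orange, horizontal marks and bars for mean ± SD (n = 2), and open points where the probe was above background on neither array of that genotype. Bmpr1a lies near 9.68 in wild type and 9.41 in knockout islets, while Sftpd moves from 9.70 to 13.88 and Slpi from 11.55 to 5.28.

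Over all 15639 tested probes, 2203 were higher and 1785 lower in knockout islets at an adjusted p below 0.05 in limma, of which 55.2% were higher. By gene, 348 rose and 484 fell at least 2-fold past the threshold. At least a 1.5-fold change with no overlap between genotypes was seen in 1768 probes upward and 1607 downward. Of the tested probes, 67.9% had no overlap in either direction. Chance gives 33.3% for unselected probes. The detection filter favours probes high on both arrays of 1 genotype, so these shares are not strictly comparable. With median scaling, which moved the median change of all tested probes from 0.05 to 0.21, 3517 were higher and 1391 lower (71.7% higher), and with cyclic loess 1832 were higher and 1884 lower (49.3% higher). Without wild type 1 the counts were 675 higher and 966 lower, and without wild type 2 they were 664 and 812.

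Genes of the Bmp and activin receptor system moved in both directions. Of 17 measured receptors, ligands and Smads, 6 rose and 3 fell (adjusted over the list alone, 7 and 3). Acvr1c, an activin-type receptor gene, rose by 3.15 ± 0.40 (SE, log2), and Bmp1, a procollagen protease gene, by 2.17 ± 0.14, although its 4 probes ranged from -0.41 to 2.28. Inhbb, an activin subunit gene detected on 1 of the 2 wild type arrays, rose by 1.10 ± 0.21, a call lost without wild type 1 (adjusted p = 0.0556). Bmpr1b, another Bmp type I receptor gene, was not well above background in knockout islets and at least 1.84-fold lower there, and Tgfbr2 and Bmp3 also fell. Among 8 measured Bmp targets and antagonists, 3 rose and 1 fell (adjusted over the list alone, 3 and 1). The leading Id4 probe was at least 3.85-fold higher, while its other tested probe changed by 0.17 and did not pass. The Bmp antagonist gene Chrd rose by 1.69 ± 0.19, Gata2 rose by 0.82 ± 0.14 and Id3 fell by 0.49 ± 0.13. Id1 changed by 0.37 ± 0.16 and Id2 by 0.13 ± 0.15, neither past the test (adjusted p = 0.136 and 0.537), and a dimmer Id2 probe fell by 0.52. Neither list passed the set test (adjusted p = 0.380 for receptors, 0.151 for targets). The list of targets and antagonists did pass by fry, as higher (median 0.33, adjusted p = 0.0297), and its median was 0.45 without knockout 2. Id3 lost its call without wild type 1, wild type 2 or knockout 2 (adjusted p = 0.157, 0.189 and 0.101) and with median scaling or the replicate block (adjusted p = 0.206 and 0.0549), and Gata2 without wild type 1 (adjusted p = 0.0705). Bmp3 lost its call without wild type 1, wild type 2 or knockout 1 (adjusted p = 0.0631 to 0.203) and with the authors' values (-0.40, adjusted p = 0.0530).

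The transcripts of the islet hormones did not pass the test. Ins2 was 15.08 ± 0.08 in wild type and 15.21 ± 0.03 in knockout islets (SD, n = 2, adjusted p = 0.482), Gcg 14.78 ± 0.02 and 14.76 ± 0.18, Sst 14.82 ± 0.01 and 14.76 ± 0.11, and Ppy 14.88 ± 0.12 and 14.95 ± 0.03. These transcripts were among the brightest on the arrays, with Ins2 at 15.24 on knockout 1 and highest raw intensities per array of 36837 to 40522. Near the top of the range a missing call therefore does not exclude a change. Quantile normalization also gives probes of the same rank the same value on every array, which limits differences among the brightest probes. Gcg and Sst took the other sign with median scaling (0.08 and 0.03), and Ppy with cyclic loess (-0.05). Of 25 measured beta cell hormone and identity genes, 3 rose and 0 fell in limma (adjusted over the list alone, 2 and 0). These were Npy, by 1.38 ± 0.12, the islet glucose-6-phosphatase gene G6pc2, by 1.13 ± 0.14, and the glucose transporter gene Slc2a2, by 0.56 ± 0.14, with its other probe at 0.23 and not past the test. Slc2a2 lost its call without any 1 of the 4 arrays (adjusted p = 0.0522 to 0.198) and with cyclic loess (adjusted p = 0.0519). Pdx1 changed by 0.25 ± 0.12 (adjusted p = 0.185), and passed with median scaling at 0.56 (adjusted p = 0.0352). Ero1b and Esr1 did not pass with their brightest probes, although another Ero1b probe fell by 2.05 and another Esr1 probe, not well above background in wild type islets, was higher past the test. The beta cell list did not pass the set test (adjusted p = 0.586), with a median of -0.01 and a mean of 0.16.

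Of 29 genes of the insulin secretion machinery, 6 rose and 2 fell (adjusted over the list alone, 8 and 2), and the list did not pass the set test (adjusted p = 0.151), but did by fry (adjusted p = 0.0297). Chgb, a secretory granule protein gene, rose by 1.71 ± 0.14, Ptprn2, another granule protein gene, by 1.04 ± 0.24 and the muscarinic receptor gene Chrm3 by 1.03 ± 0.19. Pam, which encodes the peptide amidating enzyme, fell by 1.41 ± 0.15, with its other probe at -0.20 and not past the test, and Syt7 was at least 1.28-fold lower. Gnas and Cacnb2 did not pass with their brightest probes. Another Gnas probe was at -1.68, past the test, and a further Gnas probe, not well above background in wild type islets, was higher past the test. Another Cacnb2 probe, not well above background in knockout islets, was lower past the test. Chrm3 lost its call without wild type 1 or 2 (adjusted p = 0.0516 and 0.0841), and Ptprn2 without wild type 1 or knockout 1 (adjusted p = 0.0816 and 0.0758). Of 8 alpha cell markers, 5 fell and 0 rose (adjusted over the list alone, 5 and 0), including the amino acid transporter gene Slc38a5, which fell by 1.55 ± 0.14, and Etv1, which fell by 1.27 ± 0.19. Rgs4, Slc7a2 and Peg3 also fell, with a second probe of Slc7a2 and of Peg3 not past the test (-0.25 and -0.29), while Gcg and Ttr had values of -0.02 each and took the other sign with median scaling (0.08 and 0.05). The alpha cell list was lower by camera (median -0.72, adjusted p = 0.00820; adjusted p = 0.555 with an estimated correlation). On the same arrays the median of the lymphocyte markers was -3.04 and that of the acinar markers -0.71. Rgs4, Slc7a2 and Peg3 lost their calls without wild type 1 (adjusted p = 0.0723 to 0.111) or wild type 2 (adjusted p = 0.0513 to 0.0905), and Peg3 with median scaling (-0.44, adjusted p = 0.0876). Syt7 lost its call without wild type 1, wild type 2 or knockout 1 (adjusted p = 0.0796 to 0.158) and with an offset of 50 (adjusted p = 0.0555). Of 6 delta, PP and epsilon cell markers 0 passed in limma, with the largest values at -0.63 ± 0.23 for Hhex and -0.44 ± 0.14 for Ghsr. Hhex passed without knockout 2 (-0.95, adjusted p = 0.0133) and Ghsr without knockout 1 (-0.57, adjusted p = 0.0423).

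Genes that mature beta cells normally keep silent were lower as a group. Of 22 measured, 11 fell and 2, Cxcl12 and Tst, rose (adjusted over the list alone, 11 and 2), with a median of -0.67 (camera adjusted p = 0.00162; adjusted p = 0.555 with an estimated correlation). Lmo4 fell by 1.87 ± 0.12, Zfp36l1 fell by 1.40 ± 0.12, Acot7 fell by 1.37 ± 0.26 and Hsd11b1 fell by 1.26 ± 0.18. Acot7 lost its call without wild type 1 or 2 (adjusted p = 0.0531 and 0.0867). Cxcl12 and Tst lost their calls without wild type 1 or 2 (adjusted p = 0.0728 to 0.153), and Cxcl12 without knockout 2 (adjusted p = 0.0636). Of 8 progenitor and dedifferentiation markers, Sox11 rose by 0.94 ± 0.14, and Sox9 and Aldh1a3 fell (adjusted over the list alone, 1 rose and 4 fell), with Aldh1a3 at least 1.34-fold lower. The progenitor list did not pass (adjusted p = 0.125), but did without knockout 2 (adjusted p = 0.0449). Sox9 lost its call without any 1 of the 4 arrays (adjusted p = 0.0803 to 0.210), and Aldh1a3 without wild type 2 (adjusted p = 0.125). The Sox9 call was also lost with the authors' values (-0.27, adjusted p = 0.0814), with no background correction (-0.30, adjusted p = 0.0699), and with an offset of 50, median scaling, no filter, the replicate block or an intensity trend (adjusted p = 0.0507 to 0.0696). On the same arrays the median change of the lymphocyte markers was -3.04 and that of the acinar markers -0.71.

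Lymphocyte markers had the lowest median of all lists. Of 18 measured, 17 fell (adjusted over the list alone, 17) and the brightest probe of Cd8b1, at -0.02 (0.25 with median scaling), did not pass, while its other probe, not well above background in knockout islets, was lower past the test. The pan-lymphocyte surface protein gene Cd52 fell by 3.99 ± 0.13, the leukocyte actin regulator gene Coro1a fell by 3.84 ± 0.19, and Jchain, which joins antibody units, was at least 9.73-fold lower. The median was -3.04, or -2.84 with the 7 members that were not well above background in knockout islets at their bound (camera adjusted p = 1.56e-16; adjusted p = 0.555 with an estimated correlation). Of 15 macrophage and dendritic cell markers, 7 fell and 2 rose (adjusted over the list alone, 7 and 3). The lysozyme gene Lyz1 fell by 3.78 ± 0.49 and Lyz2 fell by 3.19 ± 0.32. The antigen presentation gene Cd74 fell by 1.81 ± 0.16, with its other probe lower by 0.68, past the test, and H2-Ab1 fell by 1.68 ± 0.16. Adgre1, a macrophage surface receptor gene, and Fcer1g rose, a call that Adgre1 lost without wild type 1 or 2 (changes of 0.79 and 0.78). This list had a median of -0.31 (camera adjusted p = 0.0214; adjusted p = 0.665 with an estimated correlation and 0.0717 by fry) and lost its call without wild type 1 (adjusted p = 0.0658) and with no filter on dim probes (median -0.05, adjusted p = 0.0766). Its median was -0.20 without knockout 1 and -0.16 with median scaling, both past the test.

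Inflammatory, interferon response and cell cycle transcripts were lower on the same arrays as the lymphocyte markers, whose median was -3.04. Of 12 inflammatory and acute phase genes, 6 fell and 0 rose in limma (adjusted over the list alone, 7 and 0). The chemokine gene Ccl5 fell by 2.77 ± 0.21, and of the adhesion molecule genes Vcam1 fell by 2.45 ± 0.20 and Icam1 fell by 1.99 ± 0.14. Tnfaip3, which encodes an inhibitor of inflammatory signalling, fell by 1.5 ± 0.25, a call lost without wild type 2 (adjusted p = 0.0503). The list median was -0.94 (camera adjusted p = 0.000234; adjusted p = 0.555 with an estimated correlation). Of 13 interferon response genes, 6 fell (adjusted over the list alone, 6), among them Ifi27l2a (change -2.94 ± 0.40) and the immunoproteasome genes Psmb8 (-1.76 ± 0.15) and Psmb9 (-1.58 ± 0.13). Gbp3, a guanylate-binding protein gene, fell by 0.99 ± 0.17, a call lost without wild type 1 (adjusted p = 0.0675). Their median was -0.43 (camera adjusted p = 0.000681; adjusted p = 0.612 with an estimated correlation and 0.0711 by fry), and was -0.77 without wild type 2 and -0.25 with median scaling, both past the test. Of 26 cell cycle genes, 22 fell (adjusted over the list alone, 22), and Ccnd2, Bub1, Cdk4 and Mcm6 did not pass with their brightest probes, although another probe of Ccnd2 fell by 1.36 and another of Mcm6 fell by 0.98 past the test. The brightest Mcm6 probe, at 0.68, passed with median scaling, with the replicate block and without knockout 1 (adjusted p = 0.0217 to 0.0442). The spindle protein gene Nusap1 fell by 3.16 ± 0.27, the replication helicase gene Mcm5 fell by 2.72 ± 0.16, Cenpa fell by 2.64 ± 0.30 and Plk1 fell by 2.38 ± 0.17. The cell cycle median was -1.76, or -1.34 with the 9 members not well above background in 1 genotype at their bound (camera adjusted p = 1.16e-13; adjusted p = 0.555 with an estimated correlation).

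**Figure D2:**
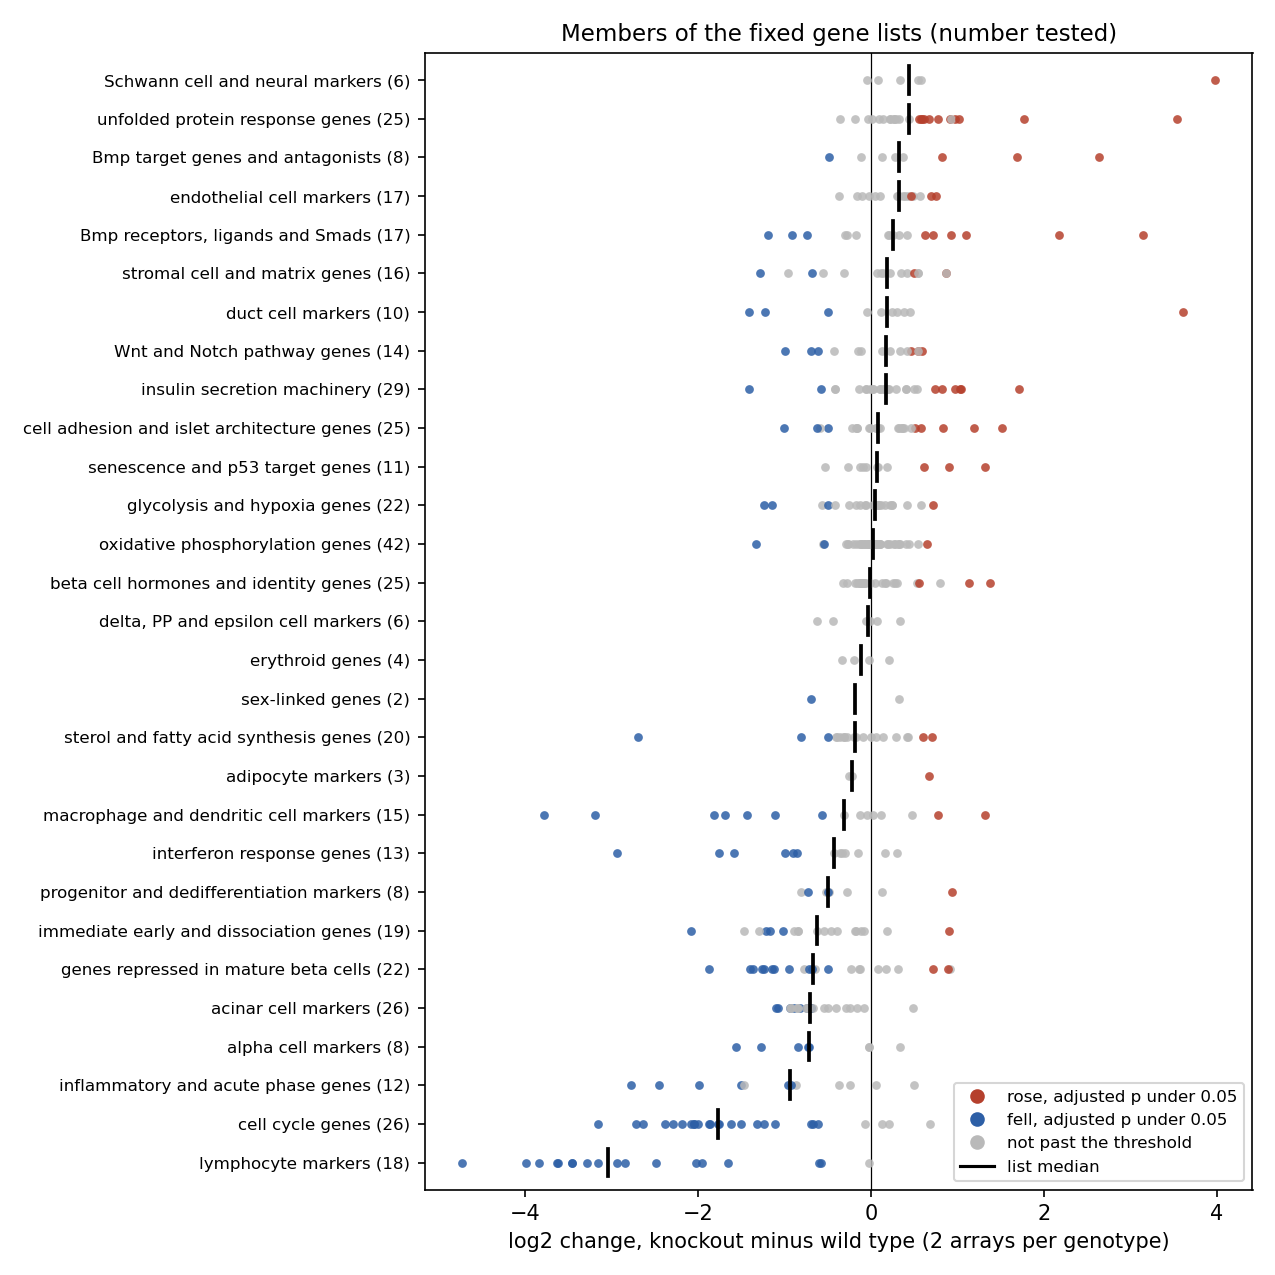
Log2 change from wild type to knockout (horizontal axis, 2 arrays per genotype) of each tested member of the fixed gene lists (vertical axis, with the number tested), red for members that rose, blue for those that fell, grey for those not past the threshold, and a black bar at the list median. The lymphocyte markers, with a median of -3.04, and the cell cycle genes, with a median of -1.76, lie farthest to the left.

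Acinar cell transcripts, which come from the enzyme-secreting tissue around islets, were lower in knockout islets. Of 26 measured, 9 fell and 0 rose in limma (adjusted over the list alone, 16 and 0), including the protease gene Ctrc (change -1.10 ± 0.24), the trypsin inhibitor gene Spink1 (-1.07 ± 0.19), the colipase gene Clps (-0.93 ± 0.16) and the carboxypeptidase gene Cpa1 (-0.89 ± 0.23). The median was -0.71 (camera adjusted p = 4.93e-06; adjusted p = 0.665 with an estimated correlation and 0.199 by fry), and the list also differed between the wild type arrays, by a median of -0.53 for wild type 1 minus wild type 2. Without wild type 2 the acinar median was -0.39, and with median scaling -0.45, both past the test. Ctrc, Spink1 and Clps lost their calls without wild type 2 (adjusted p = 0.0694, 0.0601 and 0.0749), and Ctrc without knockout 1 (adjusted p = 0.0677). Cpa1 lost its call without wild type 2 (-0.57, adjusted p = 0.149), without knockout 1 (adjusted p = 0.108) and with median scaling (adjusted p = 0.0764). Of 10 duct markers, Cftr rose and 3 fell (adjusted over the list alone, 3 rose and 3 fell). Tff2, a secreted trefoil protein gene, fell by 1.41 ± 0.32, the tight junction gene Cldn4 fell by 1.22 ± 0.12 and Sox9, with the lost calls given above, fell by 0.50 ± 0.13, and the list did not pass (adjusted p = 0.839; 0.0297 by fry, as higher). Tff2 lost its call without wild type 2 (-0.90, adjusted p = 0.0512), knockout 1 or knockout 2 (adjusted p = 0.0531 and 0.0705).

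Of 17 endothelial markers, Vwf, Flt1 and Cd34 rose (adjusted over the list alone, 1), by 0.76 ± 0.12 for Vwf and 0.70 ± 0.18 for Flt1. The endothelial list did not pass (median 0.32, adjusted p = 0.0874), but did without wild type 1 (adjusted p = 0.0211) and with no filter on dim probes (median 0.22, adjusted p = 0.0246). Vwf, Flt1 and Cd34 lost their calls without either wild type array (adjusted p = 0.0565 to 0.204), Flt1 and Cd34 also without knockout 1 (adjusted p = 0.104 and 0.0515) and Cd34 without knockout 2 (adjusted p = 0.106) and with cyclic loess, the replicate block or an intensity trend (adjusted p = 0.0545 to 0.0711). Of 16 stromal and matrix genes, Col4a1 and Col4a2 rose and Vim and Pdgfra fell (adjusted over the list alone, 2 and 2), with another Pdgfra probe at -0.24 and not past the test, and with Vim lower by a change of -1.29 ± 0.28 and Col4a2 higher by 0.87 ± 0.15 (list adjusted p = 0.618). Vim lost its call without wild type 1 or 2 (adjusted p = 0.0874 and 0.115) and was at -0.84, past the test, without knockout 1. Col4a2 lost its call without wild type 2 (adjusted p = 0.0755). Col4a1 lost its call without any 1 of the 4 arrays (adjusted p = 0.0886 to 0.241) and with cyclic loess or the replicate block (adjusted p = 0.0585 and 0.0549), and Pdgfra without wild type 1, wild type 2 or knockout 1 (adjusted p = 0.129, 0.135 and 0.0694). Among 6 Schwann cell and neural markers Ngfr, given above, rose (adjusted over the list alone, 1). The brightest Mbp probe, at 0.34, did not pass, except with median scaling (0.62, adjusted p = 0.0183), while of its other probes 1 was higher and 1 lower past the test. Th changed by 0.58 ± 0.25 (adjusted p = 0.142), passing without knockout 2 (0.93, adjusted p = 0.0232), with the replicate block (adjusted p = 0.0420) and with median scaling (0.80, adjusted p = 0.0494). The Schwann cell list did not pass (adjusted p = 0.125), but did by fry (adjusted p = 0.0297). Of 3 adipocyte markers Pparg rose by 0.67 ± 0.15 (adjusted over the list alone, 1), a call lost without wild type 2 or knockout 1 (adjusted p = 0.143 and 0.0687), and Adipoq, not well above background in knockout islets, did not pass (adjusted p = 0.188). Of 4 erythroid genes 0 passed in limma, with Hbb-bs at -0.34 ± 0.21 and Hba-a1 at 0.21 ± 0.23.

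Genes of the unfolded protein response, which adjust protein folding in the endoplasmic reticulum, were higher. Of 25 measured, 11 rose and 0 fell in limma (adjusted over the list alone, 13 and 0), with a median of 0.44 (camera adjusted p = 0.000892; adjusted p = 0.555 with an estimated correlation and 0.0535 by fry). The stress-induced pseudokinase gene Trib3 rose by 3.54 ± 0.40, the glutathione-degrading enzyme gene Chac1 by 1.77 ± 0.30, the transcription factor gene Ddit3 by 1.01 ± 0.13 and the disulfide isomerase gene Pdia6 by 0.98 ± 0.16. On the same arrays the median of the lymphocyte markers was -3.04. Pdia6 lost its call without wild type 1 (adjusted p = 0.0630), and Chac1 lost its call without wild type 1 or 2 (adjusted p = 0.0554 and 0.0623). Of 11 senescence and p53 target genes, the cyclin-dependent kinase inhibitor genes Cdkn2b and Cdkn1a rose by 1.32 ± 0.14 and 0.90 ± 0.14, and Igf1r also rose (adjusted over the list alone, 3). That list did not pass (adjusted p = 0.593). Cdkn1a lost its call without wild type 2 (adjusted p = 0.0631), and Igf1r without wild type 1, wild type 2 or knockout 1 (adjusted p = 0.119, 0.0935 and 0.0508).

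Immediate early and dissociation genes, which respond within minutes to handling of tissue, differed between the knockout arrays. The list median of knockout 1 minus knockout 2 was 1.18, against 0.05 for wild type 1 minus wild type 2. Fos was 14.47 on knockout 1 and 12.25 on knockout 2, with 14.22 and 14.19 on the wild type arrays, and Egr1 was 14.15 and 12.00, with 13.95 and 13.89. Without knockout 1 the changes were -2.0 for Fos and -1.96 for Egr1 (adjusted p = 0.00109 and 0.00116), and without knockout 2 they were 0.26 and 0.23. Of 19 measured, 4 fell and Ccn2 rose (adjusted over the list alone, 4 and 1). Of the heat shock genes, Hspa1a fell by 2.08 ± 0.18, Dnajb1 fell by 1.22 ± 0.30 and Hspb1 fell by 1.01 ± 0.18, and Egr2 was at least 1.56-fold lower. The list was lower by camera (median -0.62, adjusted p = 0.0141; adjusted p = 0.665 with an estimated correlation and 0.376 by fry), but without knockout 2 its median was 0.23 (adjusted p = 0.647) and without knockout 1 it was -1.35. Dnajb1 lost its call without wild type 1 or 2 (adjusted p = 0.149 and 0.116) and was at -0.74, past the test, without knockout 2. Hspb1 lost its call without wild type 1 (adjusted p = 0.0681) and Egr2 and Ccn2 without wild type 2 (adjusted p = 0.0717 and 0.0664).

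Cell adhesion and islet architecture genes moved in both directions. Of 25 measured, 5 rose and 3 fell (adjusted over the list alone, 6 and 3). The laminin receptor gene Itga6 rose by 1.52 ± 0.14 and Efna5, an ephrin ligand gene, by 1.19 ± 0.17, with Gja1 and Ctnnb1 also higher past the test and Lamb1 at least 1.31-fold higher. The 3 Ctnnb1 probes ranged from -0.48 to 0.51, and 1 passed. Cadm1, an adhesion molecule gene, fell by 1.01 ± 0.17. Itgb4 was at least 1.10-fold lower and Robo1 also fell. The list did not pass the set test (adjusted p = 0.586; 0.0418 by fry, as higher). Of these genes only Itga6 and Efna5 kept their calls without wild type 1, where the others had adjusted p = 0.0544 to 0.143, and without wild type 2 (0.0618 to 0.169 for the others). Ctnnb1 also lost its call without knockout 2 (adjusted p = 0.0561), and Robo1 without knockout 1 or 2 (adjusted p = 0.0562 and 0.0636) and with median scaling (-0.20, adjusted p = 0.392).

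The metabolic and signalling lists held members that moved in both directions. Of 42 oxidative phosphorylation genes, Uqcrq fell by 1.33 ± 0.18, Atp5e also fell and Atp5o was at least 1.54-fold higher (adjusted over the list alone, 0 rose and 1 fell). Of 22 glycolysis and hypoxia genes, Ldha, the lactate dehydrogenase gene, fell by 1.24 ± 0.20, the glucose transporter gene Slc2a3 fell by 1.15 ± 0.16 and P4ha1 also fell, while Egln1 rose (adjusted over the list alone, 1 rose and 3 fell). Of 20 sterol and fatty acid synthesis genes, the desaturase gene Scd1 fell by 2.69 ± 0.25 and Idi1 fell by 0.81 ± 0.16, Fdps also fell, and Sqle and Dhcr7 rose (adjusted over the list alone, 2 rose and 3 fell). Of 14 Wnt and Notch pathway genes, 3 rose (Nrarp, Notch3, Tcf7l2) and 3 fell (adjusted over the list alone, 4 and 4), with the Wnt antagonist gene Sfrp5 at least 1.37-fold lower, Ccnd1 at -0.69 ± 0.16 (4 of its 5 probes passed) and Mfng at -0.61 ± 0.16. These lists did not pass the set test (adjusted p = 0.889, 0.593, 0.251 and 0.985). Of the genes named here, Uqcrq, Slc2a3, Scd1 and Sfrp5 kept their calls under each alternative that tested them. Of the others, Ldha kept its call without wild type 1 and Egln1 without wild type 2, and the rest lost theirs without either (adjusted p = 0.0634 to 0.232 without wild type 1, 0.0634 to 0.144 without wild type 2). Calls were also lost without knockout 1 for Atp5e, P4ha1, Sqle, Fdps, Ccnd1 and Tcf7l2 (adjusted p = 0.0550 to 0.135), and without knockout 2 for Atp5o, P4ha1, Fdps, Mfng, Notch3 and Tcf7l2 (adjusted p = 0.0554 to 0.0861). Median scaling ended the calls of Atp5e (-0.23), P4ha1 (-0.25), Fdps (-0.18), Ccnd1 (-0.40) and Mfng (-0.41), with adjusted p = 0.0930 to 0.425, and cyclic loess and the replicate block those of Atp5e and Tcf7l2 (adjusted p = 0.0528 to 0.0621).

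Xist, transcribed from the inactive X chromosome, was detected on all 4 arrays, at 8.70 ± 0.13 in wild type and 8.01 ± 0.38 in knockout islets (SD, n = 2, adjusted p = 0.0496), and another Xist probe fell by 1.10. The call of the first probe was lost without wild type 1, wild type 2 or knockout 2 (adjusted p = 0.130, 0.220 and 0.107), with a change of -0.42 without knockout 2 against -0.69, and with median scaling (adjusted p = 0.161). Of the Y-linked genes measured, Eif2s3y and Kdm5d were not well above background on any array, and 1 of the 3 Uty probes was just above it on all 4, with a change of 0.32 ± 0.15 (adjusted p = 0.157). Adjusted over the list alone, Xist fell and Uty did not pass.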

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

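Of the 125 genes named by the rule, 110 passed the threshold, all 110 kept their direction under each alternative that tested them, and 63 stayed past it. Calls were lost by 30 of the 110 with no filter on dim probes (more tests), 35 and 40 without wild type 1 and 2, 16 and 10 without knockout 1 and 2, and 8 or fewer under each other alternative. Changes of the 110 were over 1.5 times smaller in 25 with the authors' values, 12 with no background correction, 7 with an offset of 50 and 5 with median scaling, where 2 were larger. With no filter on dim probes the medians of the inflammatory, mature beta cell silent, immediate early and interferon lists were -0.065, -0.32, -0.39 and -0.23 (more dim genes), and the cell cycle median was -1.10 with the stricter detection, all past the test. Sizes of dim genes depend on the signal over background, which sets what a bound can show. Probes higher in knockout islets numbered 2203 and were 3517 with median scaling, 1351 with 1 probe per gene (fewer tests), and 664 to 2212 with 1 array left out (fewer samples). Probes lower numbered 1785 and were 1012 with detection p under 0.01 on all arrays (fewer probes), 1029 with 1 probe per gene, and 812 to 1769 with 1 array left out. Probes at least 1.5-fold higher without overlap numbered 1768 and were 975 with no background correction, 1124 with an offset of 50, 2968 with median scaling, 902 with the authors' values, 826 with the stricter detection and 541 at 2-fold. Those lower numbered 1607 and were 1061 with the authors' values, 685 with the stricter detection and 823 at 2-fold. For the scalings and the authors' values the cause was not tested. Camera with an estimated correlation called 0 lists in place of 10, although 6236 probes had an unadjusted p under 0.05. For the mature beta cell silent list the estimated correlation, 0.0061, lay below the preset 0.01. Its unadjusted camera p still went from 0.000435 to 0.0677. Correlation between members therefore does not account for the loss of that call, and the cause was not tested. Fry, which does not compare a list with other genes, called 10 lists. Of these 5 were also called by camera (alpha cell, mature beta cell silent, lymphocyte, inflammatory and cell cycle). The others, all called as higher, were Bmp targets, insulin secretion, duct, Schwann cell and adhesion. Members past the threshold over the list alone numbered 189, and 121 to 198 with 1 array left out. Values that took the other sign, for which the cause was not tested, were Bmpr1a with median scaling (0.013), Gcg with median scaling (0.077) and the authors' values (0.0098), Sst, Ttr, Cd8b1 and Ero1b with median scaling (0.033, 0.051, 0.25 and 0.11) and Ppy with cyclic loess (-0.052). With 1 array left out, Gcg ranged from -0.14 to 0.11, Sst from -0.13 to 0.019, Ppy from -0.018 to 0.15, Id2 from -0.016 to 0.28, Hba-a1 from -0.069 to 0.50, Ttr from -0.052 to 0.0099, Cd8b1 from -0.15 to 0.096, Ccnd2 from -0.19 to 0.043, Ero1b from -0.38 to 0.21, Fos from -2.0 to 0.26, Egr1 from -1.96 to 0.23, and the median of the immediate early list from -1.35 to 0.23. With the replicate number as a block, 2141 probes were higher and 1776 lower, and 3643 of the 3988 calls were shared in direction. Samples of the same number did not deviate together across probes (correlation 0.02). This value, from normalized data, does not exclude a factor that samples of the same number share. A slide block was not run, since the files used here name no slides.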

Other observations

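Cish, Tnfrsf11b, Nupr1, Aldh1l2, Mthfd2 and Igf2 lie outside the fixed lists and were chosen after their values were seen. Cish, a cytokine-induced signalling inhibitor, rose by 3.41 ± 0.27 on the log2 scale (SE, adjusted p = 0.000637). Tnfrsf11b, the gene of the decoy receptor osteoprotegerin, rose by 2.95 ± 0.13, the stress-responsive gene Nupr1 by 2.24 ± 0.14 and the mitochondrial folate enzyme genes Aldh1l2 and Mthfd2 by 2.13 ± 0.15 and 1.13 ± 0.17, where Mthfd2 lost its call without wild type 1 (adjusted p = 0.0518). The growth factor gene Igf2 fell by 2.73 ± 0.13. Of 8 measured B cell and germinal centre genes outside the fixed lists, listed before their values were seen, 7 fell and Fas, at -0.60 ± 0.21, did not pass, except without knockout 2 (-0.88, adjusted p = 0.0130). Bcl6 fell by 1.99 ± 0.20, and the leading Spib probe, not well above background in knockout islets, was at least 5.51-fold lower, while its other probe fell by 0.51.

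The following tests were chosen after the changes they address had been seen, with their bounds written before the tested values were, except that the rise of Sftpd and the summary of the macrophage list, which holds the class II genes, were known, that the cell cycle test was judged undecided afterwards, and that the gut test was judged against the size of the rise afterwards. Lymphocyte and cell cycle transcripts were lower in knockout islets. Normalization between arrays is argued against, since the lymphocyte median was -2.87 with median scaling and -3.11 with cyclic loess, which replace the quantile step. It was -2.45 with no background correction and -2.47 with an offset of 50, which both keep that step. With the authors' values, whose method is not known here, it was -2.38. Lymphoid tissue carried along with the wild type islets stays open: the abundant class II transcripts Cd74, H2-Aa, H2-Ab1 and H2-Eb1, of which B cells bring much, also fell, with a median of -1.56, but the test does not separate carried-over tissue from lymphocytes inside wild type islets. Whether the cell cycle transcripts came from the same cells cannot be told apart, because the wild type arrays differed little: the medians of wild type 1 minus wild type 2, -0.175 for the cell cycle and -0.11 for the lymphocyte list, had the same sign, as that explanation predicts, but both lie close to 0. A difference in immune cells that goes with the genotype was not tested.

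The rise of Tph1, Tph2 and Cish was set against sources of such transcripts. Gut epithelium carried along with the knockout islets is argued against as the source of the whole rise, since it would bring its abundant transcripts too. Of 10 gut epithelial genes listed, 5 were tested, and their 6 tested probes had a median of -0.0232 with an SD of 0.701. Vil1 was highest (1.09, adjusted p = 0.00459), and 1 of the 2 Lgals4 probes was also higher past the test. Tff3 was lowest at -0.49 (-0.75 without knockout 1). All lay below the smallest rise to explain, 3.41 for Cish. The wild type values differed, with 8.03 for Vil1 and 6.63 for Tff3, while Tph1 was not well above background. Sizes of log2 changes are therefore not strictly comparable between these genes. A candidate explanation, as a hypothesis, is prolactin receptor signalling in the knockout islets, as in pregnancy. Of 7 genes known to rise in islets of pregnant mice or under prolactin, listed before their values were seen, 6 were measured. The receptor gene Prlr had no tested probe. Ehhadh, Socs2, Ivd, Wipi1 and Pim3 rose and Gcat, at -0.33, did not pass, with a median of 1.70. Gcat passed as lower with the authors' values and with an intensity trend (adjusted p = 0.0480 and 0.0374). Pim3 lost its call without any 1 of the 4 arrays (changes of 0.40 to 0.60). The Pim3 call was also lost with cyclic loess and the replicate block (adjusted p = 0.0541 and 0.0648). The mouse Prl and Gh probes were not well above background on any array, which cannot test hormone that comes from outside the islets. The growth hormone receptor gene Ghr was detected on all 4 arrays by its brighter probe, with a change of 0.18 ± 0.13 (SE, adjusted p = 0.346). Another Ghr probe was not well above background on any array. These values do not single out the prolactin receptor. Pregnancy, a human growth hormone sequence, which some pancreatic Cre transgenes carry, and the loss of Bmpr1a itself stay open and untested.

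Sftpd and Bmpr1a both lie on chromosome 14, so DNA of another strain around the targeted Bmpr1a allele was tested as a source of changed genes nearby. Of the 40 tested genes nearest to Bmpr1a in gene order, 8 passed the threshold, which is 20% (exact binomial 95% interval 9.05 to 35.6), against 25.5% of the other 9311 genes (Fisher's exact test, one-sided, p = 0.836). The neighbours did not hold more changed genes than the rest, and 40 genes are too few to exclude a small excess.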
